A study of Mus musculus with 10 samples.

How the data were processed

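Gene counts came from the deposited count files, 1 per library, in which the authors had counted aligned reads on genes. Per the submitters' processing notes, the tools were TopHat2 2.0.13, Cufflinks 2.2.1, HTSeq 0.6.1 and DESeq2 1.6.3, with the mm10 mouse genome. FPKM values came from the table that the authors deposited beside the counts. The gene annotation and the strand setting of the counts are not given in the sources used here, so genes that overlap on opposite strands are uncertain. The count files held 24538 genes, of which 24460 were also in the FPKM table and 7652 had 0 counts in all libraries. Their 5 non-gene rows stayed out of library sizes and tests; reads on no feature took 61.4% ± 3.97 of all counted rows in normal lung and 69.6% ± 6.6 in metastases (SD, n = 5 each). No pair of libraries was identical.

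The main test was edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default low-count filter and a robust quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values in the report are TMM-scaled, SDs cover the spread between libraries, and no CPM value is corrected for gene length. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic of this test. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, over the 36 of 40 lists that had at least 5 tested members. The list level of a library is the mean log2 CPM of the tested members, compared by an exact permutation test over all arrangements of the 10 libraries. Coordinates came from GENCODE M21 (GRCm38), in which 23830 gene symbols matched exactly 1 gene.

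The test, the gene lists, the other settings to try and the rule for named genes were fixed before the data were examined. The rule names Pecam1 and Ptprc; the 8 largest changes each way among called genes without overlap between the groups and with a mean of at least 20 CPM in the higher group; up to 4 called members of each list called by camera or with many called members; and the 2 most abundant members of each list of other cells or RNA quality. These settings were DESeq2 1.42.0, RLE and upper-quartile factors, no filter and a stricter filter, limma voom, the replicate number as a block, 3 limma fits of the FPKM table, a fold threshold of 1.5, leaving out genes of other cells, and leaving out each library. For lists they were an estimated correlation, fry, RLE factors, the stricter filter, the block, the FPKM table and each library left out. A batch term, subsets by library number, leaving out metastasis libraries 4 and 5, thinning, removal of a length and GC trend, and removal of 1% carry-over were added after the data were seen. A small number of genes, and the list level that rests on them, are not reported here.

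In a self-test on simulated counts of 11823 genes with this design, edgeR recovered 0 of 50 genes changed 2-fold, 6 of 50 changed 4-fold, 27 of 50 changed 8-fold and 29 of 50 changed 16-fold, and 4.62% of its calls were false. DESeq2 recovered 0, 17, 38 and 41 of 50, and 34.2% of its calls were false. In this simulation 11623 genes were left unchanged, whereas 20.2% of the tested genes were called in the data. With so few changed genes, the recovery and the false shares need not hold for the calls in the data. Camera recovered 2 of 2 lists shifted 4-fold and called 0 of the others. The simulated genes were drawn independently, so this does not test list calls under correlation between members. In the data that correlation was estimated at up to 0.657 (platelet and megakaryocyte genes). The common dispersion of the data was 1.03, a biological coefficient of variation of 101%, so a gene that did not pass may still differ.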

Results

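The series measured gene expression in sorted mouse cells that carried CD31 (Pecam1), an adhesion molecule of endothelial cells and platelets, and lacked CD45 (Ptprc), the common antigen of leukocytes. The cells came from normal lung (n = 5 libraries) and from dissected lung metastases (n = 5 libraries) of C57BL6/J females aged 8 to 10 weeks. The metastases grew from E0771-LG cells, a mammary carcinoma line of the same mouse strain, given into the tail vein at 6 to 8 weeks of age. Each metastasis library pooled lesions under 1 mm across from 2 to 4 mice. The labels do not say whether each normal library came from a separate mouse, so the p-values measure only the spread between these libraries. The 5 libraries of a group correlated with each other at 0.755 to 0.819 in normal lung and at 0.655 to 0.814 in metastases (Pearson's r across genes, which are not independent replicates), and at 0.516 to 0.636 between groups. The leading principal component held 34.5% of the variance and separated the groups.

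Counts on genes ran from 41004704 to 79710581 per library in normal lung and from 21677429 to 54266459 in metastases. All counted rows of a library, in units of 1e6, ran from 148.14 to 257.61, above the 60 to 80 reads (1e6) that the labels state, so what was counted is uncertain. In units of 1e6 the mean gene counts were 57.3 ± 18.8 (SD, n = 5) and 32.2 ± 13 (SD, n = 5), and they differed by an exact permutation test (two-sided, p = 0.0397). A count of 3 in these libraries corresponded to 0.0376 to 0.138 CPM (counts per 1e6 gene counts). Of all counted rows, 28.0% ± 4.53 (SD, n = 5) lay on genes in normal lung and 18.0% ± 5.76 (SD, n = 5) in metastases (exact p = 0.0317). The 10 most abundant genes took 17.7% ± 3.09 of the gene counts in normal lung and 8.48% ± 1.81 in metastases (SD, n = 5 each, exact p = 0.00794, the smallest this test allows). Malat1, an abundant nuclear RNA, alone took 7.004% ± 2.69 and 2.75% ± 1.44 (SD, n = 5 each, exact p = 0.0238). The share of Rn45s, the ribosomal RNA precursor, split the normal libraries: it was 3.51% and 2.83% in numbers 1 and 2 and 0.41% to 0.47% in numbers 3 to 5. In metastases it was 1.45% and 4.61% in numbers 1 and 2 and 0.65% to 1.24% in numbers 3 to 5.

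**Figure D1:**
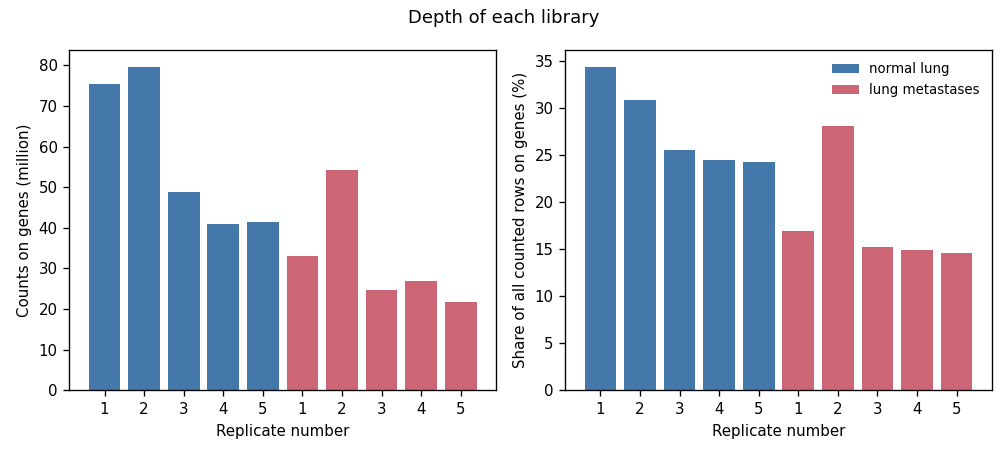
Bars give, for each library, the counts on genes (left axis, 1e6) and the share of all counted rows that lay on genes in percent (right axis); the x axis is the replicate number. Normal lung libraries held 41004704 to 79710581 counts and metastasis libraries 21677429 to 54266459.

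The design asks how CD31-positive, CD45-negative cells of metastases differ from those of normal lung. In the metastases, 26 of 34 genes of cell division and 13 of 19 of translation and ribosome production rose, and 14 of 31 genes of collagens and basement membrane rose while 2 fell (adjusted p = 0.092 with an estimated correlation for the latter list). Of genes of endothelial identity 17 of 20 fell, of general capillaries 12 of 18 and of aerocyte capillaries 16 of 18 (adjusted p = 0.198, 0.122 and 0.163 with an estimated correlation). Markers of other cells rose in the same libraries: 4 of 7 of mammary tumour cells, 7 of 12 of macrophages, 4 of 6 of fibroblasts, with 1 lower, 3 of 3 of neutrophils and 4 of 12 of platelets. Only tested members are counted, and the full lists held 17, 19, 16, 12 and 13 genes in this order. A marker low in normal lung can pass the low-count filter through the metastasis libraries alone, which favours rises. For macrophages, fibroblasts and platelets the adjusted p was 0.122, 0.129 and 0.457 with an estimated correlation. Pecam1 itself, on chromosome 11 from 106654217 to 106750628 (GRCm38, minus strand, protein-coding), fell by 1.91 on the log2 scale (SE 0.47, edgeR adjusted p = 0.00549). It stood at 644 ± 508 CPM in metastases and at 2415 ± 864 CPM in normal lung (SD, n = 5 each). The groups did not overlap, and metastasis libraries 4 and 5 held the lowest values, 239 and 146 CPM. Ptprc, on chromosome 1 from 138062861 to 138175708 (minus strand), rose by a log2 fold change of 2.77 (SE 0.57, adjusted p = 0.0012), from 17.8 ± 7.31 to 121 ± 25.6 CPM (SD, n = 5 each).

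Of 11823 genes tested with edgeR's quasi-likelihood test, 1420 were higher and 972 lower in metastases at a Benjamini-Hochberg adjusted p under 0.05, or 20.2% of those tested. The excess of higher genes depended on the setting: 1292 and 1168 passed with upper-quartile factors, 1175 and 1120 with a length and GC trend removed, and 1278 and 1194 in the limma fit of the FPKM values. Of the called genes, 1189 rose and 747 fell by at least 4-fold. No overlap between the groups was found for 1734 of all tested genes, or 14.7%, against 0.794% by chance, and 1543 of these were called. The deposited FPKM table gave the same direction for 2386 of the 2392 called genes, which is a second quantification of the same libraries and not independent data. Within library numbers 1 and 2 alone, the test called 487 genes higher and 201 lower, and within numbers 3 to 5 alone 1108 and 762; the log2 fold change of Pecam1 was -1.64 (adjusted p = 0.102) and -2.25 (adjusted p = 0.0182) in these subsets, and that of Ptprc 2.64 (adjusted p = 0.125) and 2.86 (adjusted p = 0.0159). Without metastasis libraries 4 and 5, chosen after their Pecam1 values were seen, 1137 genes were higher and 527 lower.

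**Figure D2:**
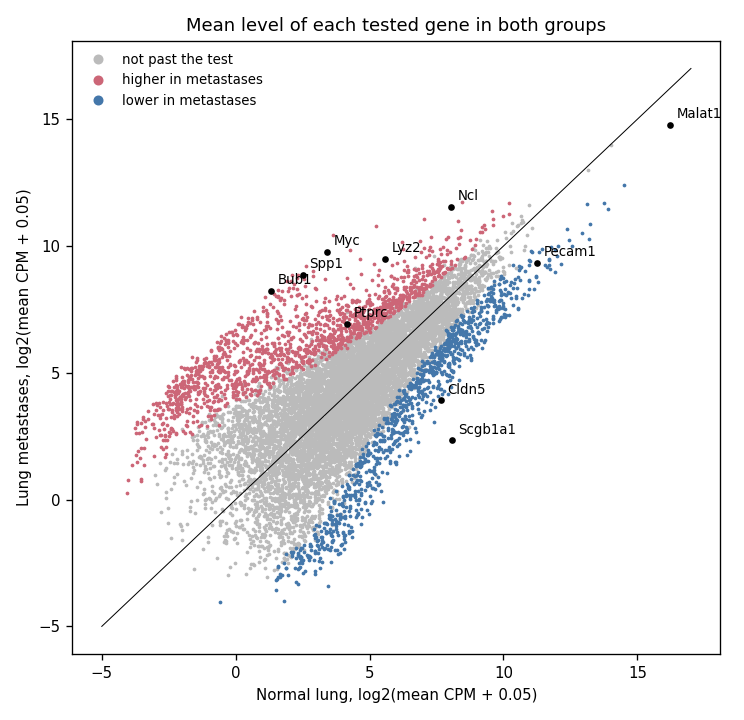
Each point is 1 tested gene, at log2(mean CPM + 0.05) over 5 normal lung libraries (x axis) and over 5 metastasis libraries (y axis); colours mark genes past adjusted p 0.05. The 1420 genes higher in metastases lie above the line of equality and the 972 lower genes below it, with Pecam1 at 2415 CPM in normal lung and 644 CPM in metastases.

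Among named genes with a mean of at least 20 CPM in the higher group and no overlap between the groups, the 8 largest rises had log2 fold changes of 7.33 to 7.59. They were Prkg2, a cGMP-dependent protein kinase (chromosome 5, 98929773 to 99037351), Nxf3, a relative of the mRNA export factors (chromosome X, 136072099 to 136085255), Pax2, a developmental transcription factor (chromosome 19, 44756045 to 44837871), Pkp2, a desmosome protein, Slc1a2, a glutamate transporter, Dtx4, Troap and the kinetochore gene Nuf2. Prkg2 rose from 0.192 ± 0.0736 to 37.6 ± 21.1 CPM (SD, n = 5 each, log2 fold change 7.59, SE 1.11, adjusted p = 3.41e-05). Nxf3 rose from 0.273 ± 0.0501 to 48.9 ± 10.97 CPM (log2 fold change 7.47, SE 0.97, adjusted p = 7.23e-06). Of 6544 genes at 20 CPM or more in metastases (mean, unscaled), none had a normal lung mean below 0.405% of that level. For 167 of them it was under 1%. The 8 rises lie near this lowest share, so their size and order are uncertain. Over the settings tried, the log2 fold change ran from 2.55 to 11.52 for Prkg2, from 3.52 to 14.10 for Nxf3 and from 1.12 to 11.85 for Slc1a2, lowest in the FPKM fits and highest with 1% carry-over removed. Under the same limits, the 8 largest falls ranged from -5.24 to -5.81 and comprised Cachd1 (chromosome 4, 100776675 to 101029220), the transporter Abcg3 (chromosome 5, 104935057 to 104982718), Zfp418 (chromosome 7, 7171330 to 7183562), Tril, the arterial gap junction gene Gja4, the complement receptor Cr2, the mitochondrial carrier Slc25a35 and the clock gene Per2. Abcg3 fell from 45.4 ± 30.4 to 0.884 ± 0.318 CPM (SD, n = 5 each, log2 fold change -5.68, SE 0.98, adjusted p = 0.000235). Pax2, Pkp2, Slc1a2, Tril and Per2 did not pass in the unfiltered fit of the FPKM values (limma adjusted p 0.0585 to 0.110).

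Of 20 tested pan-endothelial genes, 17 fell and none rose (19 fell when adjusted over the list alone), with a median log2 fold change of -2.32 and a camera adjusted p of 3.59e-09 (adjusted p = 0.198 with an estimated correlation). Cldn5, a tight junction protein of the endothelium, fell from 202 ± 229 to 15.0 ± 5.88 CPM (SD, n = 5 each), Sox18, a vascular transcription factor, from 320 ± 128 to 26.4 ± 30.9 CPM, and the secreted vascular factor Egfl7 from 273 ± 127 to 33.5 ± 16.1 CPM. The list level (mean log2 CPM of its members) was 8.70 ± 0.42 in normal lung and 6.16 ± 0.90 in metastases (SD, n = 5 each, exact p = 0.00794), with the lowest values, 5.32 and 5.15, in metastasis libraries 4 and 5.

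Of 18 general capillary genes, 12 fell and none rose (13 fell when adjusted over the list alone; camera adjusted p = 1.92e-06, and 0.122 with an estimated correlation). They included the incretin receptor Glp1r (log2 fold change -3.27), the water channel Aqp1 (-2.91) and Gpihbp1 (-2.84), which carries lipoprotein lipase to the capillary surface. Of 18 genes of aerocytes, the capillary cells specialised for gas exchange, 16 fell and none rose (17 fell when adjusted over the list alone; camera adjusted p = 3.59e-09, and 0.163 with an estimated correlation). Carbonic anhydrase Car4 fell from 630 ± 401 to 77.7 ± 62.7 CPM and Emp2 from 1501 ± 735 to 189 ± 125 CPM (SD, n = 5 each), and Tbx2 (-3.00) and Clec14a (-2.95) fell with them. These were the highest adjusted p-values of each list among the 22 settings tried.

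Of 16 tested arterial genes, 6 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.049, and 0.401 with an estimated correlation). Gja4 (-5.30) and Hey1 (-2.89), a target of Notch, fell, whereas Dkk2, a secreted modulator of Wnt signalling, rose (7.16). The call ended when any of normal libraries 1, 2 and 5 or metastasis libraries 1, 3, 4 and 5 was left out (adjusted p 0.0541 to 0.102). Of 5 tested lymphatic genes, 2 fell, Ackr2 (-3.60) and Flt4 (-3.03), and Mmrn1 rose (2.65); 3 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.049, and 0.322 with an estimated correlation). That call ended without any of normal libraries 1, 2 and 5 or metastasis libraries 3, 4 and 5 (adjusted p 0.0541 to 0.0785), and the call of Mmrn1 ended without metastasis library 1 (log2 fold change 1.77). Mmrn1 was highest in metastasis library 1 (565 CPM), as was the platelet gene Ppbp (11948 CPM). Within normal lung both were highest in library 2 (68.3 and 810 CPM). Whether lymphatic cells carried the rise of Mmrn1 is therefore open. Venous genes gave no call as a list (adjusted p = 0.777): of 12, 1 rose (Bst1 at 5.36) and 2 fell (Amigo2 at -3.63 and the receptor kinase Ephb4 at -2.90), or 2 and 2 when adjusted over the list alone, and these members were named after their values were seen. Genes of tip cells and tumour angiogenesis gave none either (adjusted p = 0.287). Of 19, 3 rose (Cd276 at 5.78, Adm at 5.23 and the matrix proteoglycan Hspg2 at 4.24) and 4 fell, among them the pericyte-recruiting factor Pdgfb (-2.89); 3 rose and 7 fell when adjusted over the list alone.

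**Figure D3:**
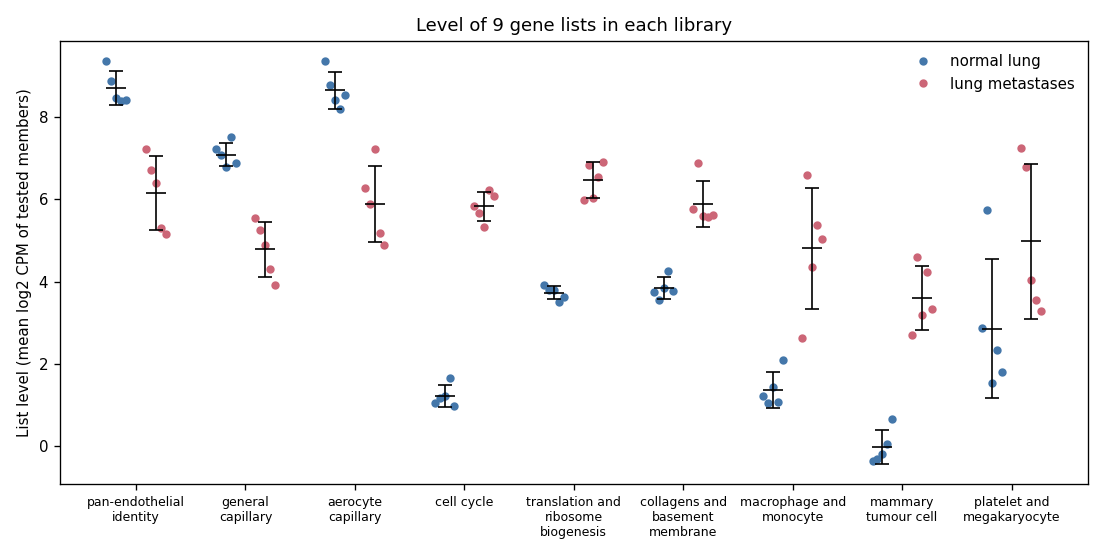
Points give the mean log2 CPM over the tested members of 9 gene lists (x axis) in each library, and black bars the mean and SD of 5 libraries. Pan-endothelial levels were 8.70 ± 0.42 in normal lung and 6.16 ± 0.90 in metastases, and cell cycle levels were 1.22 ± 0.27 and 5.83 ± 0.35.

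Cell cycle genes had the smallest camera p of all lists, with 26 of 34 members higher and none lower (28 when adjusted over the list alone) and a median log2 fold change of 4.86 (camera adjusted p = 1.27e-22). The mitotic checkpoint kinase Bub1, on chromosome 2 from 127801122 to 127831865, rose from 2.46 ± 0.40 to 301 ± 159 CPM (SD, n = 5 each, log2 fold change 6.93, SE 0.61, adjusted p = 2.75e-08). The survivin gene Birc5 (6.97), the mitotic kinase Aurkb (6.64) and the spindle motor Kif11 (6.64) rose likewise. The list level was higher in 5 of 5 metastasis libraries, at 5.83 ± 0.35 against 1.22 ± 0.27 (SD, n = 5 each, exact p = 0.00794). Genes of translation and ribosome biogenesis rose in 13 of 19 cases and none fell (14 rose when adjusted over the list alone; camera adjusted p = 3.59e-09). Myc, a transcription factor that drives cell growth, on chromosome 15 from 61985391 to 61990374, rose from 10.6 ± 2.27 to 880 ± 530 CPM (SD, n = 5 each, log2 fold change 6.38, SE 0.52, adjusted p = 8.38e-09), and nucleolin, Ncl, from 266 ± 59.0 to 2986 ± 1195 CPM. Ornithine decarboxylase, Odc1, rose by a log2 fold change of 3.59 and the RNA polymerase I subunit Polr1a by 3.30. Both calls held with an estimated correlation (adjusted p = 0.00247 each), as did those of the cytosolic ribosomal proteins and the mammary tumour cell markers, and no other list's call did.

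Genes of hypoxia and glycolysis rose in 10 of 25 cases and 1 fell (11 and 1 when adjusted over the list alone; camera adjusted p = 4.11e-06, and 0.116 with an estimated correlation). The oxygen sensor Egln3 (6.88), the lactate exporter Slc16a3 (6.14), hexokinase Hk2 (5.94) and the glucose transporter Slc2a1 (5.51) rose, and the member that fell was the growth factor Vegfa (-1.42), itself a target of hypoxia and named here after its value was seen. Of 31 genes of collagens and basement membrane, 14 rose and 2 fell (18 and 3 when adjusted over the list alone; camera adjusted p = 6.23e-05, and 0.092 with an estimated correlation). The proteoglycan Vcan, on chromosome 13 from 89655312 to 89742509, rose from 5.79 ± 1.80 to 421 ± 94.1 CPM (SD, n = 5 each, log2 fold change 6.18, SE 0.48, adjusted p = 6.13e-09), with Lamb1 (6.27), Col6a1 (6.25) and tenascin Tnc (6.22). Genes of mesenchymal transition rose in 6 of 13 cases and none fell, also when adjusted over the list alone (camera adjusted p = 0.0124, and 0.0971 with an estimated correlation). Twist1, a transcription factor of mesenchymal cells, rose from 0.338 ± 0.0965 to 39.0 ± 12.2 CPM and fibronectin, Fn1, from 25.9 ± 20.8 to 473 ± 547 CPM (SD, n = 5 each). Snai2 (3.29) rose too, but its call ended in 7 of 10 fits that left out 1 library (adjusted p 0.0609 to 0.0945). That of S100a4 (6.40) ended in 3 other settings fixed beforehand. Fibroblast markers rose beside these lists, with Pdgfra at 6.60, Dcn at 5.57 and a fibroblast list level higher by 2.83 (exact p = 0.00794). Matrix proteases and inhibitors gave no call as a list (adjusted p = 0.353): 5 of 18 rose and 3 fell (6 and 3 when adjusted over the list alone), among them Mmp3 (7.32) and Mmp15 (-4.33).

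Genes of VEGF and angiopoietin signalling were mostly lower: 10 of 16 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0335, and 0.401 with an estimated correlation). The receptor Tie1 fell (-3.02), and the co-receptor Nrp2 rose from 20.5 ± 14.0 to 234 ± 48.3 CPM (SD, n = 5 each). The call ended without normal library 2, metastasis library 4 or metastasis library 5 (adjusted p 0.0575 to 0.084). Of 18 genes of vascular tone and coagulation, 8 fell and 2 rose (8 and 3 when adjusted over the list alone; camera adjusted p = 0.0112, and 0.237 with an estimated correlation). The sphingosine receptor S1pr1, on chromosome 3 from 115710433 to 115715072, fell from 1472 ± 258 to 185 ± 65.7 CPM (SD, n = 5 each, log2 fold change -2.99, SE 0.38, adjusted p = 5.95e-06) and thrombomodulin, Thbd, from 4595 ± 850 to 625 ± 368 CPM. The protein C receptor Procr (5.02) and cyclooxygenase Ptgs2 (3.04) rose. Of 14 Notch pathway genes, 3 fell and 2 rose (4 and 2 when adjusted over the list alone; camera adjusted p = 0.049, and 0.401 with an estimated correlation). Notch4, an endothelial receptor, fell (-2.58) and the receptor Notch2 rose (2.23). This call ended in 8 of 10 fits that left out 1 library, all but those without normal library 3 or metastasis library 2 (adjusted p 0.0738 to 0.113).

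Several signalling lists held members of both directions and no call by camera. Fry called TGF-beta and BMP signalling lower (adjusted p = 0.00928) and leukocyte adhesion higher (adjusted p = 0.00126), but not Wnt or YAP genes. The leukocyte adhesion level was higher by 1.00 (exact p = 0.00794). Of 24 genes of TGF-beta and BMP signalling, 3 rose and 6 fell (3 and 9 when adjusted over the list alone; adjusted p = 0.0826), including Tgfbi (6.10) and Smad6 (-3.59). Of 15 Wnt pathway genes, 2 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.174), with Dkk2 (7.16) and Tspan12 (-2.76) among them. Of 11 YAP targets, 3 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.879), including the receptor kinase Axl (3.46) and Amotl2 (-2.90). Of 16 leukocyte adhesion genes, 6 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.379). E-selectin, Sele (6.66), and the chemokines Ccl2 (6.50) and Cxcl2 (6.13) rose, whereas the membrane-bound chemokine Cx3cl1 fell from 172 ± 117 to 8.37 ± 4.45 CPM (SD, n = 5 each).

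Markers of other cells moved with the groups. Of 7 tested genes of the mammary tumour cell list, 4 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.000709, and 0.0449 with an estimated correlation). Osteopontin, Spp1, on chromosome 5 from 104435118 to 104441050, rose from 5.61 ± 1.34 to 466 ± 146 CPM (SD, n = 5 each, log2 fold change 6.37, SE 0.48, adjusted p = 4.42e-09) and keratin Krt8 from 0.245 ± 0.0744 to 21.9 ± 13.8 CPM. The others that rose were Lcn2 (6.80) and Wfdc2 (5.10), and the call of Wfdc2 ended without metastasis library 2. Myeloid cells also express Spp1 and Lcn2, and the camera call includes both. Of 12 macrophage and monocyte genes, 7 rose and none fell (8 rose when adjusted over the list alone; camera adjusted p = 2.99e-05, and 0.122 with an estimated correlation). Lysozyme, Lyz2, rose from 47.3 ± 46.4 to 723 ± 358 CPM and the integrin Itgam from 7.92 ± 5.37 to 315 ± 267 CPM (SD, n = 5 each). C1qb (6.47), Marco (6.42) and Fcgr1 (5.37) passed too, but not every metastasis library held them. In metastasis library 1 they stood at 0.271, 0.271 and 0.372 CPM, within their normal lung range. Ccr2 (4.50 CPM) and Lyz2 (210 CPM) were above theirs. That library had the lowest list level of the metastases (2.64) and the highest Itgam (697 CPM). Of 12 neutrophil genes, only 3 had enough counts to be tested. All 3 rose, also when adjusted over the list alone, with Cxcr2 at 18.1 ± 14.4 CPM in metastases and 0.239 ± 0.0885 CPM in normal lung (SD, n = 5 each). Genes this low in normal lung can pass the low-count filter through the metastasis libraries alone, so a rise of all 3 was favoured beforehand. Of 14 genes of leukocytes at large and lymphocytes, 6 were tested. Of these 2 rose, Ptprc and Laptm5 (4.19), and none fell, while 3 rose when adjusted over the list alone. The list had a camera adjusted p of 0.0376, and 0.271 with an estimated correlation. Its call ended in 8 of 10 fits that left out 1 library, all but those without normal library 1 or metastasis library 5 (adjusted p 0.0566 to 0.172).

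Of 6 fibroblast genes, 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0336, and 0.129 with an estimated correlation). The growth factor receptor Pdgfra rose from 0.955 ± 0.386 to 92.5 ± 60.4 CPM (SD, n = 5 each) and decorin, Dcn, by a log2 fold change of 5.57, and the cytoskeletal linker Macf1, which endothelial cells also express, fell (-1.53). The list's call ended without normal library 5 or metastasis library 2 (adjusted p 0.0577 to 0.0637). That of Mfap4 ended without metastasis library 1, which held 78.4 CPM (3.59, adjusted p = 0.124), and that of Gsn without any of normal libraries 1, 4 and 5 or metastasis libraries 4 and 5 (adjusted p 0.0528 to 0.0767). Of 12 platelet and megakaryocyte genes, 4 rose and none fell (5 rose when adjusted over the list alone; camera adjusted p = 0.0139, and 0.457 with an estimated correlation). Platelet basic protein, Ppbp, stood at 354 ± 261 CPM in normal lung and 3424 ± 4808 CPM in metastases (SD, n = 5 each, log2 fold change 3.27). Metastasis library 1 held 11948 CPM, and without it the log2 fold change was 1.84. The list's call ended without normal library 3, normal library 5 or metastasis library 1 (adjusted p 0.0579 to 0.0855), and its level did not differ by the exact test (p = 0.111).

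Alveolar and airway epithelium genes gave no call as a list (adjusted p = 0.854): of 11, 2 rose and 3 fell, also when adjusted over the list alone. The club cell secretory protein Scgb1a1 was lower (-5.74), but its normal lung values ran from 3.57 to 752 CPM, and within numbers 1 and 2 the log2 fold change was 0.20. Its call also ended with limma voom, with the replicate number as a block and in the 3 FPKM fits. The falls of Abca3 (-3.67) and Hopx (-2.24) kept their calls in all 10 fits that left out 1 library. The calls of the members that rose ended for Slc34a2 without any of normal libraries 1 to 4 or metastasis libraries 1 and 3 (adjusted p 0.0828 to 0.187), and for Lamp3 without any of normal libraries 1 to 4 or metastasis libraries 2 to 4 (adjusted p 0.0549 to 0.243). Of 6 genes of pericytes and smooth muscle none rose and 1 fell, Rgs5 (-5.84, named after its value was seen), also when adjusted over the list alone (adjusted p = 0.87). Only 1 member of the mesothelium list was tested, Upk1b (3.23, adjusted p = 0.215), and it did not pass; without normal library 1, which held 1.64 CPM, its log2 fold change was 7.06 (adjusted p = 0.0229).

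Lists that bear on RNA quality and handling did not move together. Of 20 immediate early and heat shock genes, 3 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.414). Jun fell (-1.50), and Dusp1 stood at 591 ± 336 CPM in metastases and 650 ± 213 CPM in normal lung (SD, n = 5 each, adjusted p = 0.849). Of 7 nuclear and intronic RNAs, 2 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.879). Gas5 rose (1.49), and Malat1 was lower (-1.45, adjusted p = 0.0208); the call of Malat1 ended without metastasis library 2 (adjusted p = 0.0557) or 4 (adjusted p = 0.0593), with DESeq2, with RLE size factors and against a fold of 1.5. The call of Snhg1 ended in 8 of 10 fits that left out 1 library, all but those without metastasis library 1 or 2 (adjusted p 0.0715 to 0.133). That of Xist ended without any of normal libraries 3 to 5 or metastasis libraries 1, 2, 4 and 5 (adjusted p 0.0504 to 0.0956), and without metastasis library 3 its log2 fold change moved from -1.46 to -2.30. In the FPKM fits the direction of Malat1 was reversed, because the FPKM table lists it at 0 in all 5 normal libraries. Of 29 cytosolic ribosomal proteins, 9 rose and none fell, also when adjusted over the list alone (camera adjusted p = 5.40e-07, and 0.0233 with an estimated correlation). Rpl4 rose from 149 ± 42.7 to 917 ± 149 CPM and Rpl32 from 12.5 ± 7.41 to 127 ± 14.8 CPM (SD, n = 5 each). These genes have many processed pseudogenes, so their counts are uncertain. None of the mitochondrial mRNAs was among the features of the count files.

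**Figure D4:**
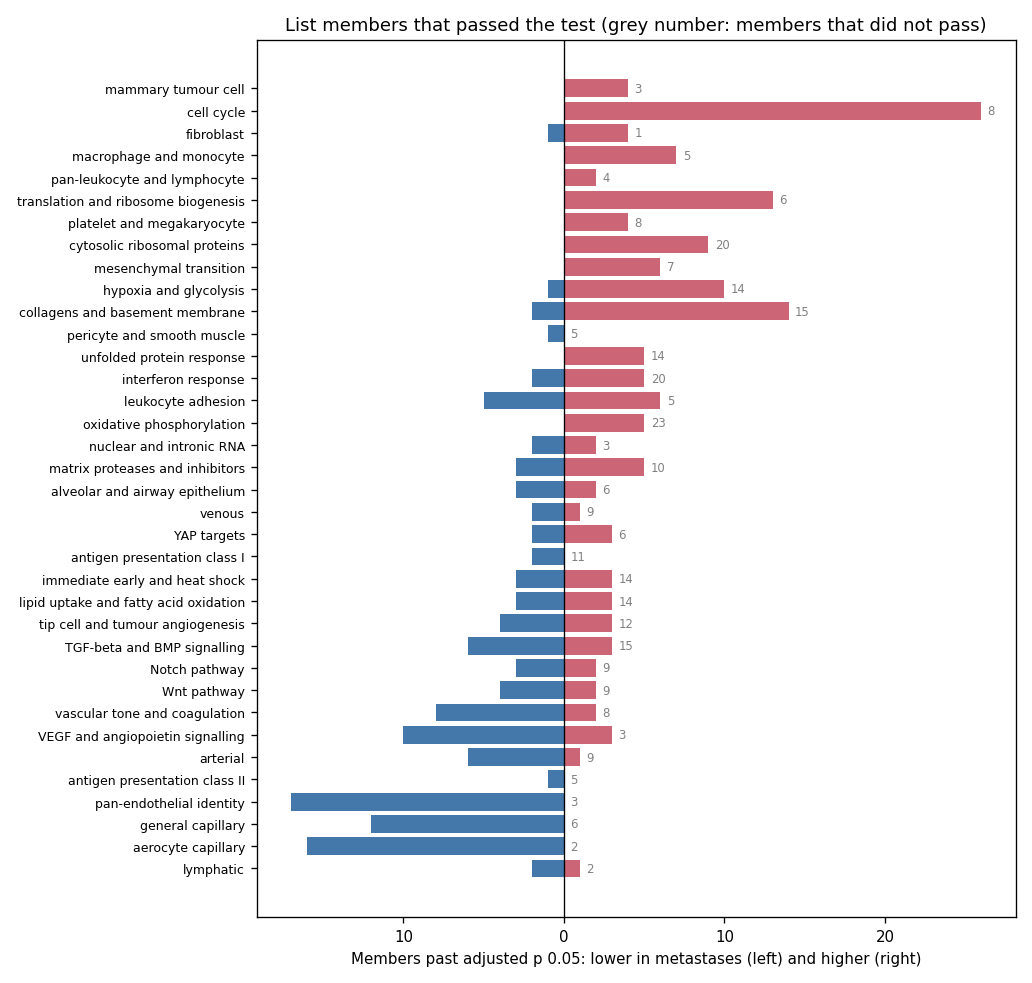
Bars count, for each of 36 lists, the tested members past adjusted p 0.05 that were lower (left) or higher (right) in metastases, and the grey number counts members that did not pass. Cell cycle had 26 higher and 0 lower members, and pan-endothelial identity 0 higher and 17 lower.

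The other lists gave no call by camera in the main fit. Their members named here lie outside the naming rule and were chosen after their values were seen. Fry called interferon response (adjusted p = 0.00282) and the unfolded protein response (0.00933) higher, class I genes (0.0295) lower, and no other list of this paragraph. The interferon level was higher by 1.04 (exact p = 0.00794). Camera called class II genes without normal library 3 (adjusted p = 0.0252). It called the unfolded protein response without normal library 1 (0.0440) or 4 (0.0494). Interferon response genes rose in 5 of 27 cases and fell in 2 (7 and 2 when adjusted over the list alone; adjusted p = 0.0625); the chemokine Cxcl10 (4.22) and the antiviral Rsad2 (3.45) rose, and Irf1 (-1.99) and Gbp4 (-1.96) fell. Of 28 genes of oxidative phosphorylation, 5 rose and none fell, also when adjusted over the list alone (adjusted p = 0.36), led by cytochrome c1, Cyc1 (3.32). Of 19 genes of the unfolded protein response 5 rose and none fell (7 and 1 when adjusted over the list alone; adjusted p = 0.0826), among them the chaperone Hspa5 (1.72). Lipid uptake and fatty acid oxidation genes went both ways, with 3 of 20 higher and 3 lower (3 and 5 when adjusted over the list alone; adjusted p = 0.375), and the fatty acid transporter Cd36 (-2.27) was among those that fell. Of 13 genes of class I antigen presentation, 2 fell, H2-Q4 (-3.33) and H2-K1 (-1.18), whose counts are uncertain because of close paralogs, and none rose (adjusted p = 0.117). Of 6 class II genes 1, the invariant chain Cd74, fell (-3.22; adjusted p = 0.0826), both also when adjusted over the list alone. In the lists of venous genes, tip cells, lipid uptake, YAP targets, alveolar epithelium, pericytes and nuclear RNAs, the median, the mean or the test differed in sign.

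Camera called 11 of the 36 lists higher and 8 lower in metastases. With a correlation between members estimated from the data, 4 were called higher and 0 lower, with 11 lists at an unadjusted p under 0.05, and fry called 13 higher and 10 lower. Leaving out each library in turn gave 8 to 12 lists higher and 4 to 9 lower.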

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

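The tests of depth, gene length and GC content, the batch of library numbers, and the 3 of cell mixture, were chosen only after the results they concern were seen. A Dixon test in each group of 5 libraries picked out 29 values among 364 groups tested, where 18.2 were expected by chance, and 10 of them lay in metastasis library 2. In metastasis library 2 the log2 CPM of Nuf2 was low at 2.66, and those of Mmp15 (2.13), Mmp14 (8.11) and Abca3 (3.88) were high. The levels of collagens (6.88) and of immediate early genes (6.27) were high there too. That library also had 28.17% of all counted rows on genes, 57.87% on no feature and 0.33% ambiguous. Of its gene counts, 4.61% lay on Rn45s. Each of these values lay away from the other 4 metastasis libraries. In normal library 1, Prkg2 (-1.45), Emp2 (11.46), Upk1b (0.75) and with it the mesothelium level (0.75) were high, and Mfap4 (-3.73) and Snhg1 (5.16) were low. In normal library 2, Slc1a2 (-2.96) and Notch2 (4.53) were low, while the levels of VEGF signalling (8.23) and vascular tone (7.36) and the numbers of genes with a count (14481) and with 10 counts (12691) were high. The others were Adm in normal library 4 (0.76, high), Egln3 in normal library 3 (-1.51, high) and metastasis library 1 (-0.95, low), Hk2 in normal library 5 (1.72, high), Axl in metastasis library 1 (5.66, low), and S1pr1 (6.24) and Lcn2 (1.43) in metastasis library 5 (both low). No library was removed for these values.

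Endothelial genes were lower and tumour, leukocyte and cell cycle genes higher in metastases (adjusted p = 0.198 for pan-endothelial, 0.271 for leukocyte and 0.122 for macrophage genes with an estimated correlation), and tumour cells among the sorted cells are a candidate explanation that stays open. The level of the mammary tumour cell list without Spp1 and Lcn2, which myeloid cells also express, was higher by 2.57 (exact p = 0.00794; 2.44 ± 1.11 against -0.14 ± 0.43, SD, n = 5 each) over 5 members, but this rise is part of the pattern and decides nothing; Cdh1, Muc1 and Erbb2 overlapped normal lung, the call of Wfdc2 ended without metastasis library 2 (3.50, adjusted p = 0.117), and Epcam reached only 5.73 CPM in metastases and 8.71 in normal lung (unscaled CPM). A lower endothelial share alone would raise all other cells alike only if lesions and normal lung held the same mix of other cells. Macrophage genes rose by 3.42 more than alveolar genes (exact p = 0.0159). The 2 tissues may differ in that mix, so this value cannot decide whether a lower endothelial share is enough. The cell cycle level was higher by 4.61 (exact p = 0.00794), which may come from dividing endothelial, tumour, myeloid or fibroblast cells, although the gate on CD31 and CD45 selects against the last 3; fibroblast genes had a level higher by 2.83 (exact p = 0.00794). Which cells carry these transcripts stays open, since the counts are of mixed sorted cells and no profile of E0771-LG cells was used here.

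A total of 91 genes were private to 1 library, at 50 CPM or more and at least 10 times the next, and their median level in the other libraries was 0.481% of that in the highest. Carry-over of reads between libraries could leave such traces, and the prediction written for it (a slope above 0.5) was met by a slope of 1.503 (bootstrap interval 1.21 to 1.93). That prediction was too wide, because carry-over alone gives a slope of 1, which the interval leaves out; the reading was therefore changed to undecided after the value was seen. Of the 91 genes, 5 had 0 counts in at least 1 other library, and 0 had 0 counts in all of them. The median share was 0.389% for genes at 50 to 100 CPM in the highest library and 2.35% at 500 CPM or more. Among genes with a mean of at least 20 CPM in 1 group (unscaled), 0 stood under 0.1% of it in the other group. Removal of 1% carry-over left 1232 genes higher and 798 lower, and whether real low expression or carry-over sets these levels stays open.

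The 2392 calls could owe something to depth, to gene length and GC content or to the batch of library numbers. With all libraries thinned to the lowest depth 2269 genes passed, and with the length and GC trend removed 2295. These counts argue against the depth of gene counts and against length and GC content as the main source. Thinning does not change the share of counted rows on genes, which was 18.0% in metastases and 28.0% in normal lung. Whether that difference adds to the calls was not tested. Within numbers 3 to 5 alone, where this batch does not vary, 1870 genes passed. Each group held all 5 numbers, so by design this batch could not itself separate the groups, and that count decides nothing. Among 100 of the 126 possible splits of the libraries into 5 and 5, only 1, the true split, reached 1420 genes higher and only 1 reached 972 lower, and the highest count of any other split was 2. For lists, 4 splits reached 11 in the larger direction, and 20 reached 8 with a highest value of 11, which meets what was written beforehand for chance, but 16 of the 19 other splits that reached 8 kept 4 of 5 libraries of each group together and so carry much of the difference. Chance is thus neither shown nor excluded for the 8 lists lower.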

How the results depend on the processing

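The cause of each difference below was not tested. Of 126 called named genes, 106 kept the call when each library was left out in turn. In every setting fixed beforehand that tested them, 92 kept it, and filters left some genes out of some settings. Of 19 called lists, 12 kept the call when each library was left out. DESeq2 called 2380 genes higher and 1661 lower, and limma voom called 1608 lower. With an estimated correlation 4 lists were higher and 0 lower. Upper-quartile factors moved the median log2 fold change of all genes from 0.06 to -0.08. The log2 fold change of Malat1 was 11.29 in the FPKM fit, 14.61 with the smaller pseudocount and 11.29 without a filter, where its normal values are listed at 0. With numbers 1 and 2 only, 487 genes were higher and 201 lower, 4 lists were lower, Scgb1a1 was 0.20, and the mean log2 differences of venous, alveolar and pericyte genes were 0.0859, 1.24 and 1.35. Without metastasis libraries 4 and 5, 527 genes and 4 lists were lower, Dusp1 was 0.21, and venous, YAP, alveolar and pericyte genes were 0.14, 0.43, 0.73 and -0.0700. Pericyte genes were 0.64 after thinning, 5 lists were lower after removal of carry-over, and the nuclear RNA level was 0.76 with the median. Leaving out each library gave -0.55 to 0.0223 for Dusp1, -0.41 to 2.13 for Postn and 4 to 9 lists lower. The list means ranged over 0.14 to 0.52 for YAP, -0.25 to 0.61 for alveolar, -0.54 to 0.48 for pericyte and -0.25 to 0.42 for nuclear RNA genes. The levels ranged over -0.43 to 0.38 for alveolar, -0.61 to 0.11 for pericyte and -0.31 to 0.19 for nuclear RNA genes. Equal library numbers gave little sign of pairing, with a mean correlation of 0.0521 against -0.0130 for unequal numbers and 1 of 5 over 0.1. Yet 3 of 5 normal and 2 of 5 metastasis libraries correlated best with their own number, so pairing is not excluded. With the number as a block, 1435 genes were higher and 1180 lower.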

Other observations

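The lists of this part and the tests of relative endothelial levels were chosen only after the results were seen. Of 20 tested genes of serine, one-carbon and amino acid supply, 14 rose in metastases, none fell and 6 did not pass, with a median log2 fold change of 4.46 and no test of the list. Psat1, an enzyme of serine synthesis, rose from 3.94 ± 1.25 to 327 ± 119 CPM (SD, n = 5 each, log2 fold change 6.38, adjusted p = 1.05e-08). Bcat1, which starts the breakdown of branched-chain amino acids (6.70), and the transporters Slc7a5 (6.42) and Slc7a11 (5.75) rose without overlap between the groups. Psph (27.5 ± 25.7 against 3.42 ± 6.45 CPM, adjusted p = 0.111) and Slc3a2 (0.39, adjusted p = 0.593) did not pass.

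Of 15 tested genes of the circadian clock, 3 rose, Bhlhe41 (4.77), Nfil3 (4.33) and Bhlhe40 (2.92), and 1 fell, Per2 (-5.24), while 11 did not pass. Per2 ranged from 2.94 to 66.1 CPM in normal lung and from 0.377 to 1.04 CPM in metastases.

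Relative to the pan-endothelial level, and without shared members, venous genes were higher by 2.23 (exact p = 0.00794, adjusted p = 0.0198) and tip cell genes by 2.24 (exact p = 0.00794, adjusted p = 0.0198), in 5 of 5 metastasis libraries each. The relative levels of general capillary genes (0.24, exact p = 0.349), aerocyte genes (-0.22, exact p = 0.468) and arterial genes (1.26, exact p = 0.0714, above the normal mean in 4 of 5 libraries) did not pass, which leaves a difference open. By the exact test the venous and tip cell levels themselves did not differ between the groups (-0.31, p = 0.548, and -0.30, p = 0.540). The relative rises thus reflect the fall of the pan-endothelial level (-2.54), and any list that did not fall would give them. Among members, 2 of 12 venous and 4 of 19 tip cell genes fell. A few large rises, such as Bst1 (5.36) and Cd276 (5.78), weigh on the list means. Against a shift among endothelial cells stands that Cd276, Adm and Hspg2 may also be expressed by tumour cells, and this stays open.

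The FPKM values of 3 genes were listed at 0 in libraries where they had at least 100 CPM (unscaled). Malat1 was at 0 in all 5 normal libraries, with 37290 to 91792 CPM there, and at 1098 to 8233 FPKM in metastases. Calcrl was at 0 in normal library 3 only, with 15857 CPM, and Rn45s in normal libraries 1 and 2 and metastasis library 2.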
